A study of Mus musculus with 8 samples.

How the data were processed

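RNA from sorted dendritic cells grown from mouse bone marrow was hybridised to 8 one-colour Agilent arrays with 60-base probes. The 4 groups combined genotype (wild type, WT, or miR-155 knockout, KO) with state (unstimulated or stimulated with lipopolysaccharide, LPS), with 2 arrays per group. Groups and replicate numbers were taken from the sample labels, which do not say whether replicates came from separate animals or cultures. The arrays lay on 2 slides of 4 arrays. Slide 1 held both WT unstimulated arrays, WT LPS replicate 2 and KO unstimulated replicate 2. Slide 2 held WT LPS replicate 1, KO unstimulated replicate 1 and both KO LPS arrays. Each of the comparisons within a genotype or within a state was therefore only partly balanced over the slides.

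Per the file headers, the authors extracted the scans with Agilent Feature Extraction 10.5.1.1, and the deposited scanner values are intensity values: a processed signal after background subtraction and spatial detrending, the raw mean signal and the local background median of each spot, on a linear scale and not scaled between arrays. The deposited spot flags, an other unit with values of 0 or 1, mark spots well above background, saturated spots and outlying spots. The deposited series table holds log2 values, which the labels do not describe further. Checked against the scanner values of the same array, the deposited table was the log2 processed signal minus a constant for each array, with column 75th percentiles of 9.19. The build in the headers was mm9, and coordinates are those written in the files.

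Each array had 45018 spots, of which 1639 were controls, and 41174 distinct probes remained without controls. Between 50.8% and 58.3% of spots were well above background on each array, and no spot was saturated. The number of arrays, 2 per group, limits the precision. Spots marked as outlying, 120 to 174 per array, were left out. The processed signal was put on the log2 scale and the 75th percentile of each array was subtracted, giving the scaled log2 signal. A probe was kept when it was well above background on both arrays of at least 1 group, which left 23739 probes. For each gene name the probe with the highest mean signal was used, which gave 15401 genes, 48 of them with a missing value on at least 1 array. Of 5687 genes with several probes past the filter, probes of 6 were called in opposite directions for the LPS response of WT and probes of 8 for that of KO, and of 0 in the comparisons between genotypes. Of 12110 tested probes with a RefSeq accession, 11967 matched the reference list of accessions and symbols.

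A linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8) for reading. The residual degrees of freedom were 4 and the prior degrees of freedom from empirical Bayes moderation were 2.88. The 6 comparisons were the LPS response in WT, the LPS response in KO, KO against WT in the unstimulated state, KO against WT after LPS, KO against WT averaged over both states, and the difference between the LPS responses of KO and WT. P values were two-sided and adjusted over all genes of a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Errors are standard errors from the limma fit, with n = 2 arrays per group. The agreement of the LPS responses was described by the correlation across genes, which are not independent replicates.

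A fitted log2 value of a gene that was not well above background on either array of a group depends on signals near the background. For such a gene a fold change is given as a lower bound, written as at least N-fold. The mean of the bright group was compared with the mean of the dim group, for which each array contributed the higher of its lowest well-above-background signal and the gene's own signal.

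A total of 30 gene lists with 661 members were fixed before the data were examined. They covered interferon-stimulated genes, inflammatory cytokines, chemokines, DC maturation and co-stimulation, NF-kB feedback and signalling, endocytic and pathogen receptors, both classes of MHC presentation, cell cycle, sterol biosynthesis, oxidative phosphorylation, glycolysis, arginine and nitric oxide metabolism, the unfolded protein response, stress and dissociation genes, published miR-155 targets, genes neighbouring Mir155 on chromosome 16, and reference genes. The remaining lists held markers of dendritic cells, plasmacytoid DC, macrophages, monocytes, neutrophils, eosinophils, mast cells with basophils, B cells, T cells, NK cells, erythroid cells and stromal cells. Some genes stand in more than 1 list. Each list was tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, then with the correlation estimated from the residuals and with the rotation test fry. Single members were also adjusted over the list alone.

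Named genes followed a rule written before the data were examined. It took, among called genes whose groups did not overlap and that carried a gene symbol, the 10 with the largest rise and the 10 with the largest fall. It added up to 4 members of each list with the smallest p, a fixed set of genes linked to miR-155 or to dendritic cell cytokines, every call with a symbol in comparisons with fewer than 10 calls, and, without a call, the genes of smallest p up to 10 in all. Clone names and probe identifiers outside that rule are named only where a count was small or a locus was examined, and were chosen after their values were seen. No probe on the array carried a name of the Mir155 host transcript, so the knockout was not checked directly.

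The alternatives tried were quantile normalisation, median scaling, normexp background correction with an offset of 50, the deposited log2 values as the source, no filter on dim probes, a filter requiring signal on all 8 arrays, every probe tested on its own, trend and robust moderation, a 2-fold minimum, slide or replicate number as a block, each slide alone, only the 4 arrays of a comparison, and leaving out each array. Chosen after seeing the data were a repaired normexp correction, a filter on detection in both groups, a replicate block within each state, and a search for the miR-155 seed match in the 60-base probe sequences. The planned search of 3′ untranslated regions was not run, because no transcript sequences were available.

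The model was tested on simulated data with the groups and array numbers of the study, 15353 genes and 200 changed genes. Values were drawn independently for each gene and array, without slide or replicate structure. It recovered 1.5% of 2-fold, 41.8% of 4-fold and 97% of 16-fold changes for the LPS response in WT. Between genotypes in the unstimulated state it recovered 3%, 46.3% and 98.5%, and for the difference between LPS responses 0%, 0% and 81.8%. False calls numbered 10, 5 and 4 in these comparisons. A simulated list shifted by 0.5 on the log2 scale passed camera, and 1 of 100 unshifted lists passed 0.05. As the simulated genes were uncorrelated, the simulation did not test the preset correlation or the rate of false calls under shared variation. The Benjamini-Hochberg threshold depends on how many genes change. The recovery given for the LPS response therefore need not apply to the data, where 3106 genes were called in WT.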

Results

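Gene expression was measured in dendritic cells (DC) from male C57BL/6Jax mice, WT or lacking the microRNA miR-155. Total bone marrow was cultured for 7 days with 40 ng/mL of the growth factor GM-CSF. Part of the cells then received 100 ng/mL LPS, a bacterial cell wall component that activates DC, for 16 h. DC were sorted by flow cytometry as CD86-negative cells from unstimulated cultures and as CD86-positive cells from stimulated cultures. The comparison of LPS with the unstimulated state therefore also compares the 2 sort gates. Each of the 4 groups had 2 arrays. Between 50.8% and 58.3% of spots were well above background, and the 75th percentile of the processed signal lay between 474 and 750 intensity units. The first principal component held 75.55% of the variance and separated all 4 LPS arrays from all 4 unstimulated arrays. The second held 9.57% and separated the arrays of replicate number 1 from those of replicate number 2, at positive and negative scores respectively.

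The first question was which transcripts differed between activated and resting WT DC. Il6, a pro-inflammatory cytokine, rose by 12.72 ± 0.25 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 5.69e-06 by limma) and was well above background on only 1 of the 2 unstimulated arrays. Il12b, the shared subunit of IL-12 and IL-23, rose at least 2548-fold, Lcn2, an iron-sequestering antibacterial protein, at least 1572-fold, and Il12a, the other IL-12 subunit, at least 389-fold. Ptgs2, the inducible cyclooxygenase, rose by 11.01 ± 0.93 with 1 of 2 unstimulated arrays well above background. Asgr2, a subunit of the asialoglycoprotein receptor, fell by 7.45 ± 0.46 (adjusted p = 0.000325). Clec10a, a galactose-binding lectin, fell by 6.74 ± 0.92, and Alox5, which makes leukotriene precursors, fell by 6.33 ± 0.35.

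Further large rises in WT were at least 434-fold for Slc1a2, a glutamate transporter, 366-fold for Slfn4 and 210-fold for Cxcl5, a neutrophil-attracting chemokine. Oasl1, an interferon-induced antiviral gene, rose by 9.54 ± 0.35, and Ms4a4d by 9.37 ± 1.02, the latter well above background on 1 of 2 unstimulated arrays. Genes lost from detection after LPS fell at least 59.0-fold (Fam64a), 47.4-fold (Cd207, the Langerhans cell lectin), 46.1-fold (Il1rl1, the IL-33 receptor), 34.0-fold (Slc36a2), 30.3-fold (Cyp2s1), 23.6-fold (Dscam) and 23.3-fold (Depdc1b). Of the fixed genes, Il1b rose by 6.10 ± 0.74, Tnf by 3.85 ± 0.39 and Socs1, an inhibitor of cytokine signalling, by 3.99 ± 0.68. Inpp5d, which encodes the phosphatase SHIP1, fell by 1.34 ± 0.26 (adjusted p = 0.0149), and Bach1, a transcriptional repressor, fell by 1.64 ± 0.35. Il23a rose at least 1.89-fold (adjusted p = 0.0494). Il10 was at least 3.86-fold higher (adjusted p = 0.104) and Arg2 had a log2 difference of 2.12 ± 1.18 (adjusted p = 0.253), without a call. No call was made for Cebpb (0.79 ± 0.31), Tab2 (0.60 ± 0.27), Jarid2 (0.19 ± 0.33) or Sfpi1 (−0.40 ± 0.35). Cd86, the sorting marker, was 3.85 ± 0.55 higher.

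Genes of the innate response rose as groups in WT. Of 46 measured interferon-stimulated genes, 44 rose and 0 fell (46 rose adjusted over the list alone), with a median log2 change of 4.09 (camera adjusted p = 4.08e-35). The antiviral genes Rsad2 and Ifit1 rose by 9.02 ± 0.33 and 7.88 ± 0.25. Of 22 inflammatory cytokines 16 rose (17 adjusted over the list alone), with a median of 3.85, or 2.61 with 9 dim members at their bound (adjusted p = 1.16e-11). The cell-death ligand Tnfsf10 rose at least 18.0-fold. Of 29 DC maturation and co-stimulation genes 22 rose (25 adjusted over the list alone; median 2.84, adjusted p = 2.37e-14). Cd40 rose by 8.02 ± 0.74, Cd200 by 6.34 ± 0.44 and Tnfrsf9 by 5.46 ± 0.39, the last with 1 of 2 unstimulated arrays well above background. Of 28 NF-kB feedback and signalling genes 21 rose (25 adjusted over the list alone; median 2.35, or 2.27 with 1 dim member at its bound, adjusted p = 3.82e-14). Tnfaip3, an inhibitor of NF-kB, rose by 3.55 ± 0.35, Cflar, an inhibitor of death receptor signalling, by 3.66 ± 0.28 and Ptges, a prostaglandin synthase, by 6.57 ± 0.40. These 4 lists also passed with an estimated correlation, at adjusted p = 0.0497, 0.0441, 0.0497 and 0.0497.

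Chemokine and MHC class I genes rose in number, but their list tests depended on the correlation. Of 24 chemokines 14 rose (15 adjusted over the list alone) with a median of 3.91 (adjusted p = 8.95e-10, and adjusted p = 0.13 with an estimated correlation). Ccl22, which attracts regulatory T cells, rose by 7.02 ± 0.31, and the CXCR3 ligands Cxcl9 and Cxcl11 at least 112-fold and 44.7-fold. Of 20 MHC class I genes 15 rose (17 adjusted over the list alone; median 1.5, adjusted p = 1.07e-08, and adjusted p = 0.0918 with an estimated correlation). The peptide transporter subunit Tap1 rose by 2.81 ± 0.30, the transactivator Nlrc5 by 2.92 ± 0.34, Tapbp by 1.94 ± 0.26 and Psme2 by 2.04 ± 0.28. Of 18 MHC class II genes, 1 rose and 4 fell (2 and 4 adjusted over the list alone), and the list did not pass (median −0.31, adjusted p = 0.258). H2-DMa, a peptide-loading chaperone, fell by 2.35 ± 0.24, the protease gene Lgmn fell by 1.65 ± 0.30 and H2-DMb2 fell by 1.53 ± 0.32, and March1, a ubiquitin ligase for MHC class II, rose by 1.23 ± 0.29. Endocytic and pathogen receptors went both ways, with 8 of 38 rising and 5 falling (the same numbers adjusted over the list alone). The mannose receptor gene Mrc1 fell by 5.73 ± 0.51 and Clec4a2 fell by 3.37 ± 0.31, whereas Tlr1 rose by 4.02 ± 0.38 and the scavenger receptor gene Marco by 5.49 ± 0.70. That list's median was −0.04 and its test pointed up (adjusted p = 0.613).

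Cell cycle and sterol biosynthesis genes fell in WT after LPS. Of 36 cell cycle genes 23 fell and 1 rose (27 and 1 adjusted over the list alone), with a median of −2.94, or −2.75 with 2 dim members at their bound (adjusted p = 1.16e-11, and adjusted p = 0.304 with an estimated correlation). The mitotic kinase gene Aurkb fell by 3.77 ± 0.36, Cdca8 fell by 3.07 ± 0.32, Kif20a fell by 4.36 ± 0.51 and Kif11 fell at least 8.02-fold. Of 22 sterol biosynthesis genes 11 fell and 0 rose (17 fell adjusted over the list alone; median −1.80, adjusted p = 9.98e-07, and adjusted p = 0.458 with an estimated correlation). Dhcr7, Nsdhl and Mvd, enzymes of cholesterol synthesis, fell by 3.88 ± 0.56, by 2.26 ± 0.35 and by 1.89 ± 0.28, and Stard4, a sterol carrier, fell by 2.04 ± 0.31. Of 36 oxidative phosphorylation genes 6 fell and 0 rose (3 fell adjusted over the list alone; median −0.69, adjusted p = 2.93e-05, and adjusted p = 0.458 with an estimated correlation). Ndufb5 and Ndufb8, complex I subunits, were at −1.79 ± 0.25 and −1.11 ± 0.25. Of 22 glycolysis genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.508). Eno2 rose by 2.37 ± 0.54, with 1 of 2 unstimulated arrays well above background, Hif1a rose by 1.43 ± 0.34, Aldoc fell by 2.65 ± 0.35 and Pdk1 fell by 1.47 ± 0.33.

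Of 13 arginine and nitric oxide genes 3 rose (3 adjusted over the list alone; median 0.40, adjusted p = 0.0952). Nos2, the inducible nitric oxide synthase, rose at least 25.9-fold, its cofactor enzyme Gch1 by 2.61 ± 0.26 and the arginine transporter Slc7a2 by 5.73 ± 0.78. Of 21 unfolded protein response genes 2 rose, Chac1 by 2.29 ± 0.63 and Asns by 2.06 ± 0.59 (0 adjusted over the list alone; median 0.65, adjusted p = 0.0244, and adjusted p = 0.483 with an estimated correlation). That call was lost without WT unstimulated replicate 2 (median 0.40) and without WT LPS replicate 2 (median 0.76). Of 18 stress and dissociation genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.64, adjusted p = 0.199). The heat shock genes Hspa1a, Hspa1b and Hsph1 rose by 3.64 ± 0.63, 3.61 ± 0.73 and 2.26 ± 0.51, while Fos fell by 2.74 ± 0.70. Of 60 published miR-155 targets 5 rose and 12 fell (6 and 12 adjusted over the list alone; median −0.15, adjusted p = 0.357). E2f2, a cell cycle transcription factor, fell by 6.03 ± 0.48 and the kinase gene Ikbke rose by 1.93 ± 0.29. Of 16 neighbours of Mir155 on chromosome 16, 5 rose (6 adjusted over the list alone; median 0.74, adjusted p = 0.00483, and adjusted p = 0.458 with an estimated correlation). Jam2, a junctional adhesion molecule, rose at least 50.5-fold, Samsn1 by 3.30 ± 0.45, Usp25 by 1.81 ± 0.31 and Btg3 by 1.69 ± 0.30. Of 14 reference genes only Gusb was called, and it fell by 1.1 ± 0.24 (list median −0.21, adjusted p = 0.258).

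Markers of other cell types also moved with LPS in WT. Macrophage markers had 2 of 17 rising and 7 falling (2 and 8 adjusted over the list alone; median −1.77, adjusted p = 0.00832, and adjusted p = 0.483 with an estimated correlation). Cd163 fell at least 8.44-fold, and the complement gene C1qa fell by 3.80 ± 0.57. Eosinophil markers fell in 2 of 4 (3 adjusted over the list alone; median −2.85, or −1.76 with 1 dim member at its bound, adjusted p = 0.0166, and adjusted p = 0.304 with an estimated correlation). Siglec5 fell by 4.41 ± 0.52 and Prg2 at least 4.70-fold, and the list did not pass without WT LPS replicate 2 (median −2.48). Stromal markers rose in 4 of 7 (4 adjusted over the list alone; median 3.42, or 2.66 with 3 dim members at their bound, adjusted p = 0.0202, and adjusted p = 0.232 with an estimated correlation). The matrix genes Dcn and Lum rose at least 40.8-fold and 6.32-fold, Pdgfrb by 3.92 ± 0.69, with 1 of 2 unstimulated arrays well above background, and Vcam1 by 3.42 ± 0.94. Without WT unstimulated replicate 2 the stromal median was 2.12. The other marker lists did not pass. DC markers had 1 of 16 rising and 5 falling (3 and 6 adjusted over the list alone; median 0.06, mean −0.83, test pointing down, adjusted p = 0.366). Ccr7, the lymph node homing receptor, rose by 6.66 ± 0.92, Ffar2 fell by 5.52 ± 0.61, Naaa fell by 3.02 ± 0.41 and Clec9a fell at least 4.02-fold. Monocyte markers had 1 of 9 rising and 3 falling (2 and 3 adjusted over the list alone; median 0.57, mean −0.93, test pointing down, adjusted p = 0.758). The chemokine receptor gene Ccr2 fell by 5.96 ± 0.48, Fn1 fell by 2.09 ± 0.57, F13a1 fell at least 17.4-fold and Ms4a6d rose by 3.52 ± 0.42.

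Neutrophil and precursor markers had 2 of 10 rising and 2 falling in WT (2 and 2 adjusted over the list alone; median −0.38, mean 1.17, test pointing up, adjusted p = 0.814). Camp rose at least 11.4-fold, Ctsg fell at least 5.33-fold and Chi3l3 fell by 1.16 ± 0.25. Mast cell and basophil markers had 2 of 8 rising and 4 falling (2 and 5 adjusted over the list alone; median −2.31, adjusted p = 0.242). Hdc, the histamine-forming enzyme, rose by 9.17 ± 1.59 with 1 of 2 unstimulated arrays well above background. Cd200r3 fell by 4.21 ± 0.65 with 1 of 2 LPS arrays well above background, and Prss34 and Mcpt8 fell at least 19.8-fold and 7.92-fold. B cell markers had 2 of 7 falling (2 rising and 3 falling adjusted over the list alone; median −1.14, adjusted p = 0.508). Ighm fell by 6.04 ± 1.07 and Fcrla fell by 2.49 ± 0.70, each with 1 of 2 LPS arrays well above background. T cell markers had 1 of 6 rising and 2 falling (2 and 2 adjusted over the list alone; median −0.18, adjusted p = 0.882). Lck rose at least 3.56-fold, and Cd2 and Lat fell at least 4.46-fold and 3.83-fold. NK cell markers fell in 2 of 4 (1 rose and 2 fell adjusted over the list alone; median −2.10, adjusted p = 0.258). Klra8 fell by 2.64 ± 0.49 with 1 of 2 LPS arrays well above background, and Klrb1c at least 2.65-fold. Plasmacytoid DC markers rose in 2 of 7 (median 0.64, adjusted p = 0.258). Bst2, which is also interferon-induced, rose by 3.35 ± 0.29 and Tcf4 by 1.65 ± 0.36. Erythroid markers rose in 1 of 7 (3 adjusted over the list alone; median 1.02, adjusted p = 0.258), Car1 by 1.86 ± 0.42.

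In all, limma called 3106 of 15401 genes in WT, 1460 higher and 1646 lower after LPS, and 3002 of these changed at least 2-fold. At an unadjusted p under 0.05 the number was 5347. In 3099 of the calls both arrays of 1 group lay above both arrays of the other, which chance gives for 33.3% of unselected genes. Calling itself selects for such a separation, so it adds no support to the calls. A fit with slide as a block called 2175 genes, and within slide 1 alone 1533, with WT LPS replicate 2 as the single LPS array. Without WT LPS replicate 1, WT LPS replicate 2 or WT unstimulated replicate 1 the counts were 1546, 1442 and 1797. Blocked by slide, the medians of interferon-stimulated genes, cytokines, DC maturation genes and NF-kB genes were 4.31, 3.91, 3.09 and 2.26, and within slide 1 they were 4.20, 3.79, 3.06 and 2.33. Those of chemokines, MHC class I, cell cycle, sterol and oxidative phosphorylation genes were 3.37, 1.68, −2.59, −1.54 and −0.67 with the block and 3.75, 1.72, −2.85, −1.34 and −0.62 within slide 1. Macrophage, eosinophil and stromal markers and the neighbours of Mir155 had medians of −1.88, −2.92, 2.92 and 0.52 with the block and −2.10, −3.31, 3.39 and 0.60 within slide 1.

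The next question was how DC without miR-155 responded to LPS. Il6 rose by 13.17 ± 0.25 (SE, n = 2 arrays per group, adjusted p = 4.49e-06), Oasl1 by 11.02 ± 0.35 and the antiviral gene Rsad2 by 10.32 ± 0.33. Il12b rose at least 4739-fold, Lcn2 at least 2491-fold, Cxcl5 at least 839-fold, Ms4a4d at least 683-fold, Il12a at least 634-fold and Slfn4 at least 470-fold, and Ptgs2 rose by 11.38 ± 0.93 with 1 of 2 unstimulated arrays well above background. Il1rl1 fell at least 103-fold, Cyp2s1 at least 55.4-fold, Fam64a at least 42.6-fold, Dscam at least 40.6-fold, Sept3 and Slc36a2 each at least 25.5-fold and Grap2, a T cell receptor adaptor, at least 23.5-fold. Asgr2 fell by 7.19 ± 0.46, E2f2 fell by 6.65 ± 0.48, and Cdh1, the adhesion molecule E-cadherin, fell by 6.56 ± 0.86 with 1 of 2 LPS arrays well above background. Of the fixed genes, Il1b rose by 6.69 ± 0.74, Tnf by 4.11 ± 0.39, Socs1 by 3.87 ± 0.68, Arg2, a mitochondrial arginase, by 5.17 ± 1.18, Cebpb by 1.23 ± 0.31, Tab2 by 1.05 ± 0.27 and Il23a at least 4.99-fold. Il10 (adjusted p = 0.0607), Fos (−2.20 ± 0.70, adjusted p = 0.0687), Inpp5d (−0.80 ± 0.26, adjusted p = 0.0747) and Bach1 (−0.59 ± 0.35, adjusted p = 0.283) were not called in KO. Cd86, the sorting marker, was 3.88 ± 0.55 higher.

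All 46 interferon-stimulated genes rose in KO (46 adjusted over the list alone; median 4.23, adjusted p = 4.92e-36), Ifit1 by 9.56 ± 0.25. Cytokines rose in 16 of 22 (18 adjusted over the list alone; median 4.28, or 3.46 with 8 dim members at their bound, adjusted p = 5.77e-12). DC maturation genes rose in 23 of 29 (25 adjusted over the list alone; median 3.24, adjusted p = 3.31e-14), Cd40 by 8.42 ± 0.74. NF-kB genes rose in 24 of 28 (25 adjusted over the list alone; median 2.52, or 2.35 with 1 dim member at its bound, adjusted p = 9.88e-15), Irg1, an itaconate-forming enzyme, by 7.24 ± 0.68 and Ptges by 6.33 ± 0.40. These 4 lists gave adjusted p = 0.0475, 0.0426, 0.0475 and 0.0475 with an estimated correlation. Chemokines rose in 14 of 24 (16 adjusted over the list alone; median 3.68, adjusted p = 8.65e-09, and adjusted p = 0.156 with an estimated correlation). Ccl5 rose by 8.71 ± 0.56, Ccl22 by 7.15 ± 0.31 and Cxcl9 at least 186-fold. MHC class I genes rose in 17 of 20 (17 adjusted over the list alone; median 1.73, adjusted p = 2.01e-08, and adjusted p = 0.0978 with an estimated correlation), Tap1 by 2.84 ± 0.30 and Tap2 by 1.78 ± 0.26. MHC class II genes had 1 of 18 rising and 4 falling (2 and 4 adjusted over the list alone; median −0.20, adjusted p = 0.357), with H2-DMa at −2.71 ± 0.24. Endocytic receptors had 6 of 38 rising and 6 falling (7 and 7 adjusted over the list alone; median 0.03, adjusted p = 0.832), with Marco up by 6.86 ± 0.70 and Mrc1 at −5.68 ± 0.51.

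Cell cycle genes fell in 24 of 36 in KO and 0 rose (30 fell and 1 rose adjusted over the list alone; median −2.81, or −2.79 with 2 dim members at their bound, adjusted p = 1.36e-12, and adjusted p = 0.305 with an estimated correlation). Aurkb fell by 3.92 ± 0.36 and Kif11 at least 11.7-fold. Sterol genes fell in 12 of 22 (17 adjusted over the list alone; median −1.82, adjusted p = 1.84e-07, and adjusted p = 0.441 with an estimated correlation). Mvd fell by 2.11 ± 0.28. Oxidative phosphorylation genes fell in 4 of 36 (1 adjusted over the list alone; median −0.51, adjusted p = 0.00079, and adjusted p = 0.5 with an estimated correlation), with Uqcrc1 at −0.93 ± 0.24 and Atp5d at −0.91 ± 0.24. Glycolysis genes had 2 of 22 rising and 1 falling (2 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.678). Arginine and nitric oxide genes rose in 4 of 13 (4 adjusted over the list alone; median 0.41, adjusted p = 0.0656), Nos2 at least 28.5-fold. Unfolded protein response genes rose in 3 of 21 (2 adjusted over the list alone; median 0.62, adjusted p = 0.0656), Dnajb9 by 1.43 ± 0.32, Ddit3 by 1.19 ± 0.29 and Chac1 by 2.23 ± 0.63. Stress genes rose in 5 of 18 (6 rose and 3 fell adjusted over the list alone; median 0.89, adjusted p = 0.122), Dnaja1 by 1.53 ± 0.40. Of 60 published miR-155 targets 9 rose and 8 fell (11 and 9 adjusted over the list alone; median −0.03, adjusted p = 0.903), and Pik3r1, a PI3-kinase subunit, rose by 1.28 ± 0.24. Neighbours of Mir155 rose in 5 of 16 and fell in 1 (6 and 1 adjusted over the list alone; median 0.62, adjusted p = 0.0524): Jam2 rose by 5.81 ± 0.64, with 1 of 2 unstimulated arrays well above background, and Mrpl39, a mitochondrial ribosomal protein gene, fell by 4.71 ± 0.32. Of 14 reference genes 1 fell (median −0.34, adjusted p = 0.223).

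Macrophage markers had 2 of 17 rising and 7 falling in KO (2 and 8 adjusted over the list alone; median −1.47, adjusted p = 0.0159, and adjusted p = 0.5 with an estimated correlation). Cd163 fell at least 9.66-fold, C1qa fell by 3.12 ± 0.57, and the lipid receptor gene Trem2 fell by 3.0 ± 0.60. The macrophage list did not pass without KO LPS replicate 2 (median −0.70). Eosinophil markers fell in 2 of 4 (3 adjusted over the list alone; median −2.30, or −1.31 with 1 dim member at its bound, adjusted p = 0.0192, and adjusted p = 0.31 with an estimated correlation), with Ear1 at −1.56 ± 0.38. Stromal markers rose in 3 of 7 (4 adjusted over the list alone; median 2.96, adjusted p = 0.0192, and adjusted p = 0.218 with an estimated correlation), Dcn at least 97.3-fold and Lum at least 20.9-fold. No other marker list passed. Among cells of the myeloid line these were DC (1 of 16 rising and 5 falling, median −0.32, adjusted p = 0.223), monocyte (1 of 9 and 3, median −0.06, adjusted p = 0.815), neutrophil (2 of 10 and 1, median −0.16, mean 1.33, test pointing up, adjusted p = 0.788) and mast cell with basophil (2 of 8 and 4, median −2.17, adjusted p = 0.187) markers. The others were plasmacytoid DC (2 of 7 rising, median 0.12, adjusted p = 0.399), B cell (1 of 7 and 1, median −0.62, adjusted p = 0.782), T cell (1 of 6 and 2, median −0.35, mean 0.29, test pointing down, adjusted p = 0.815), NK cell (2 of 4 falling, median −2.33, adjusted p = 0.154) and erythroid (1 of 7 rising, median 0.71, adjusted p = 0.205) markers. Among their members, Ccr7 rose by 7.24 ± 0.92, Hdc by 8.87 ± 1.59, Bst2 by 3.79 ± 0.29, Camp at least 19.9-fold and Lck at least 6.29-fold. Ccr2 fell by 6.55 ± 0.48, F13a1 fell by 3.67 ± 0.74 with 1 of 2 LPS arrays well above background, and Mcpt8 fell at least 6.39-fold. Lower bounds of the falls were 5.74-fold for Klra8, 5.61-fold for Clec9a, 3.95-fold for Cd2, 3.68-fold for Lat, 3.49-fold for Ltf, 3.24-fold for Cpa3 and 2.35-fold for Klrb1c.

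The test called 3208 of 15400 genes for the LPS response in KO, 1595 higher and 1613 lower, with 5267 at an unadjusted p under 0.05 and 3119 at a minimum change of 2-fold. The fit with slide as a block called 2351 genes, and within slide 2 alone 441, with KO unstimulated replicate 1 as the single unstimulated array. Without KO LPS replicate 1, KO LPS replicate 2 or KO unstimulated replicate 2 the counts were 1813, 1785 and 1420. Blocked by slide, the same medians for interferon-stimulated genes, cytokines, DC maturation genes and NF-kB genes were 4.49, 4.26, 3.21 and 2.48, and within slide 2 they were 4.53, 4.25, 3.23 and 2.49. Those of chemokines, MHC class I, cell cycle, sterol and oxidative phosphorylation genes were 3.19, 1.86, −2.60, −1.53 and −0.47 with the block and 2.80, 1.92, −2.69, −1.79 and −0.57 within slide 2. Macrophage, eosinophil and stromal markers had medians of −1.73, −2.14 and 2.46 with the block and −1.58, −1.76 and 1.98 within slide 2.

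**Figure D1:**
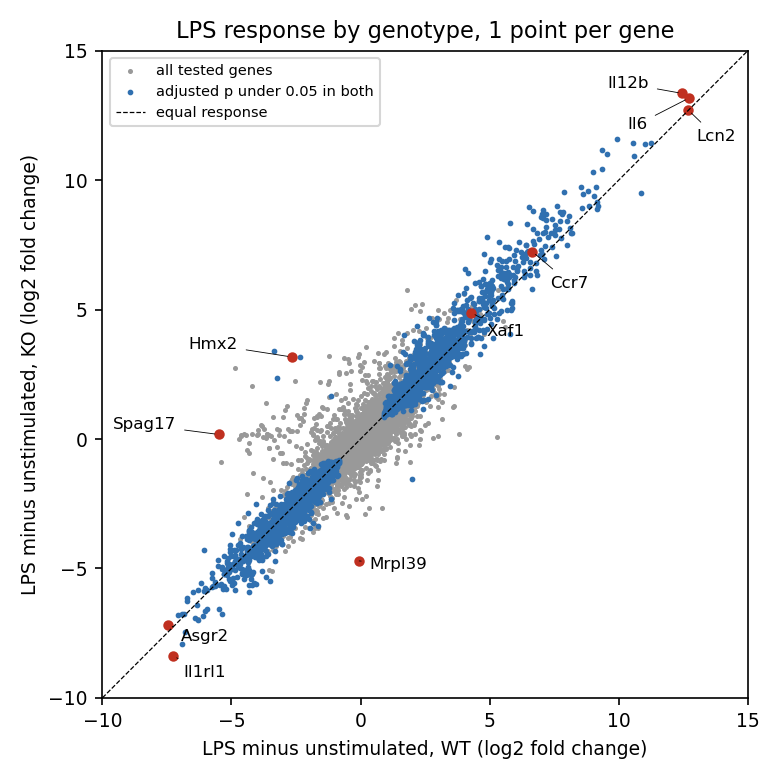
Log2 fold change with LPS in WT (horizontal axis) against KO (vertical axis), with each tested gene as a grey point, genes with an adjusted p under 0.05 in both genotypes in blue, named genes in red, and a dashed line of equality. Il6, Il12b and Lcn2 lie at the upper right, Asgr2 and Il1rl1 at the lower left, and Mrpl39, Xaf1, Hmx2 and Spag17 are named for comparison with the line.

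The responses of both genotypes were close to each other across genes. Pearson's r of the 15400 pairs of log2 changes was 0.944, Spearman's rho 0.918 and the slope of KO on WT 0.989. Of the calls, 2624 were shared with the same direction, 1270 higher and 1354 lower, where independent sets would share 151 and 172. A further 476 genes were called in WT alone and 578 in KO alone, which does not show that their responses differed. Of the WT calls 98.4% had the same sign in KO. Responses from 1 unstimulated and 1 LPS array per genotype gave r between 0.699 and 0.914 over 16 combinations, with an SD of 0.0574.

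**Figure D2:**
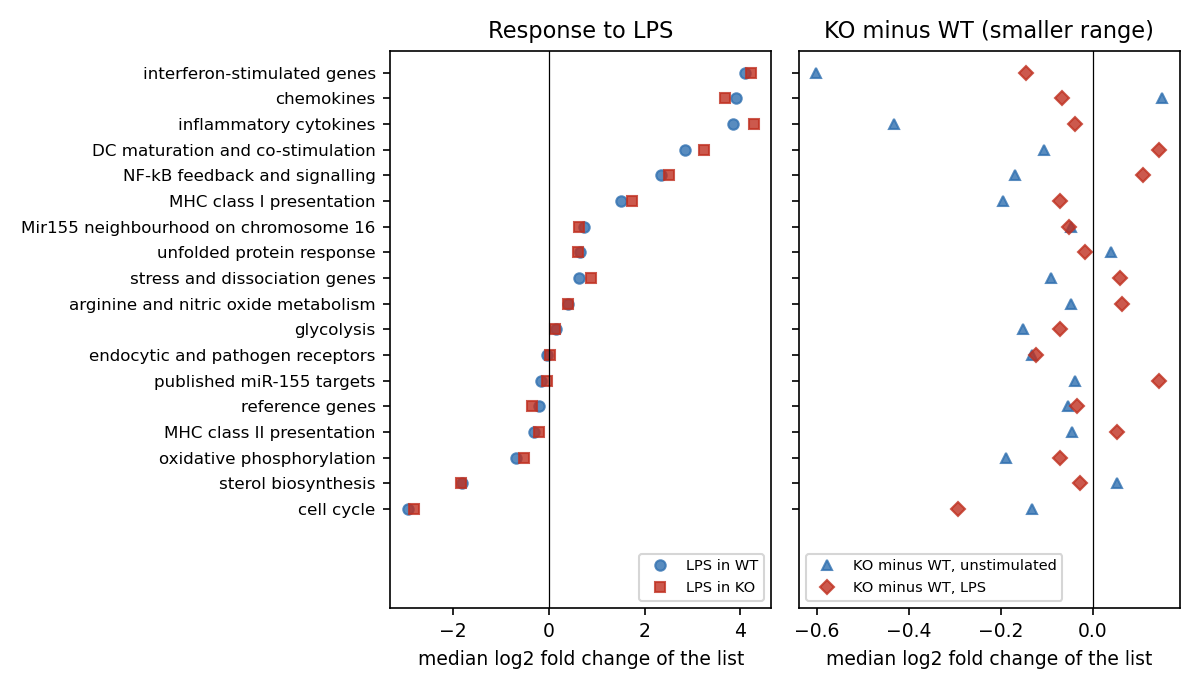
Median log2 fold change of the members of 18 fixed gene lists, with the LPS response in WT (circles) and KO (squares) in the left panel and KO minus WT in the unstimulated state (triangles) and after LPS (diamonds) in the right panel, which has a smaller range. Interferon-stimulated genes reach 4.09 and 4.23 in the left panel and −0.60 and −0.14 in the right panel.

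The next question was what differed between KO and WT in resting DC. Xaf1, an interferon-induced gene linked to apoptosis on chromosome 11 (72120129 to 72122142), was lower in KO, at a log2 difference of −3.41 ± 0.27 (SE, n = 2 arrays per group, adjusted p = 0.0096), with group means of the scaled log2 signal of 0.88 in WT and −2.53 in KO. Rtp4, an interferon-induced chaperone gene on chromosome 16 (23613668 to 23613727), was lower by a log2 difference of −2.53 ± 0.28 (means 2.78 and 0.26, adjusted p = 0.0267), while after LPS its means were 6.85 and 6.83. Nlrp1a, an inflammasome sensor gene on chromosome 11 (70910764 to 70912423), was at least 6.03-fold lower in KO (adjusted p = 0.0399). Wdfy1, an adaptor gene of endosomal receptor signalling on chromosome 1 (79701982 to 79702041), was higher in KO by 1.95 ± 0.25 (adjusted p = 0.0489). Its other probes went both ways, with differences of 2.77 and −1.24.

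In this comparison 37 of 15401 genes were called, 3 higher and 34 lower in KO. At an unadjusted p under 0.05 the number was 394, a smaller share of the genes than the 0.05 expected without any difference. In all 37 both arrays of 1 genotype lay above both arrays of the other, a separation that calling selects for. Of the 34 lower genes, 30 were not well above background on any unstimulated KO array, and 27 were well above background in no group but unstimulated WT. Among all probes, 46 were well above background on both unstimulated WT arrays and no others, 171 on both unstimulated KO arrays and no others, and other pairs of arrays had 3 to 202 such probes. Among the genes not detected in KO were Ctsr, a cathepsin gene, at least 15.4-fold lower, and Spag17, a sperm and cilia gene on chromosome 3 (99853073 to 99853131), at least 12.5-fold lower. Smaller bounds held for Mov10l1, a germ-line helicase gene (6.32-fold), Nipsnap3a (5.22-fold), Akap4, a sperm tail gene (4.81-fold), Prex2 (4.42-fold), Col4a1, a basement membrane collagen gene (4.08-fold), Kcnmb1 (3.28-fold) and Casc1 (3.07-fold). Krt1, a keratin gene, had a log2 difference of −4.27 ± 0.44 (adjusted p = 0.0226) with 1 of 2 KO arrays well above background. The other genes higher in KO were the transcript AK035714 and the unnamed probe A_52_P541760, at least 6.12-fold and 2.49-fold. Only 5 of the 37 were well above background in both groups, and a fit of the 13772 genes detected in both groups called 0 (158 at an unadjusted p under 0.05).

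Interferon-stimulated genes were lower as a group in unstimulated KO: 42 of 46 had lower means, with a median log2 difference of −0.60 (camera adjusted p = 1.74e-21). With an estimated correlation the list did not pass (adjusted p = 0.471), nor with fry (adjusted p = 0.224). Xaf1 was its only member past the test, 5 members were lower adjusted over the list alone, and without Xaf1 the median was −0.59. Ifit1, Oasl2 and Rsad2 had differences of −1.71 ± 0.25, −1.88 ± 0.33 and −1.56 ± 0.33, with adjusted p of 0.0962, 0.219 and 0.471. The median was −0.44 with slide as a block and −0.40 within slide 1, where KO unstimulated replicate 1 is the unstimulated array left out. Inflammatory cytokines had a median of −0.43 with 17 of 22 lower and 0 past the test (0 adjusted over the list alone; adjusted p = 0.0349, and adjusted p = 0.488 with an estimated correlation), or −0.28 without the 9 members dim in both groups. That median was −0.43 with the slide block and −0.55 within slide 1, and the list did not pass with any 1 of the 4 unstimulated arrays left out (medians from −0.79 to −0.34). Oxidative phosphorylation genes had a median of −0.19 with 35 of 36 lower and 0 past the test (0 adjusted over the list alone; adjusted p = 0.0102, and adjusted p = 0.991 with an estimated correlation), and medians of −0.24 and −0.36 with the block and within slide 1. It did not pass without WT unstimulated replicate 1 (median −0.10) or without KO unstimulated replicate 2 (median 0.0). The other 27 lists, published miR-155 targets among them (median −0.04, 22 higher and 38 lower, adjusted p = 0.988), did not pass, and 0 of their members were called.

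When slide was a block 5 genes were called, Spag17, NAP100574-001, AK082037 and AK089089 at an adjusted p of 0.0412 and AK034179 at 0.048. In that fit Xaf1 had −3.26 ± 0.28 (adjusted p = 0.0634), Rtp4 −2.34 ± 0.27 (adjusted p = 0.121) and Wdfy1 1.82 ± 0.26 (adjusted p = 0.186). Within slide 1 Xaf1 had −3.32 and limma called 0 genes (260 at an unadjusted p under 0.05). Without KO unstimulated replicate 1 or replicate 2 the count was 0 (361 and 511 at an unadjusted p under 0.05), and without any other array 12 to 26.

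**Figure D3:**
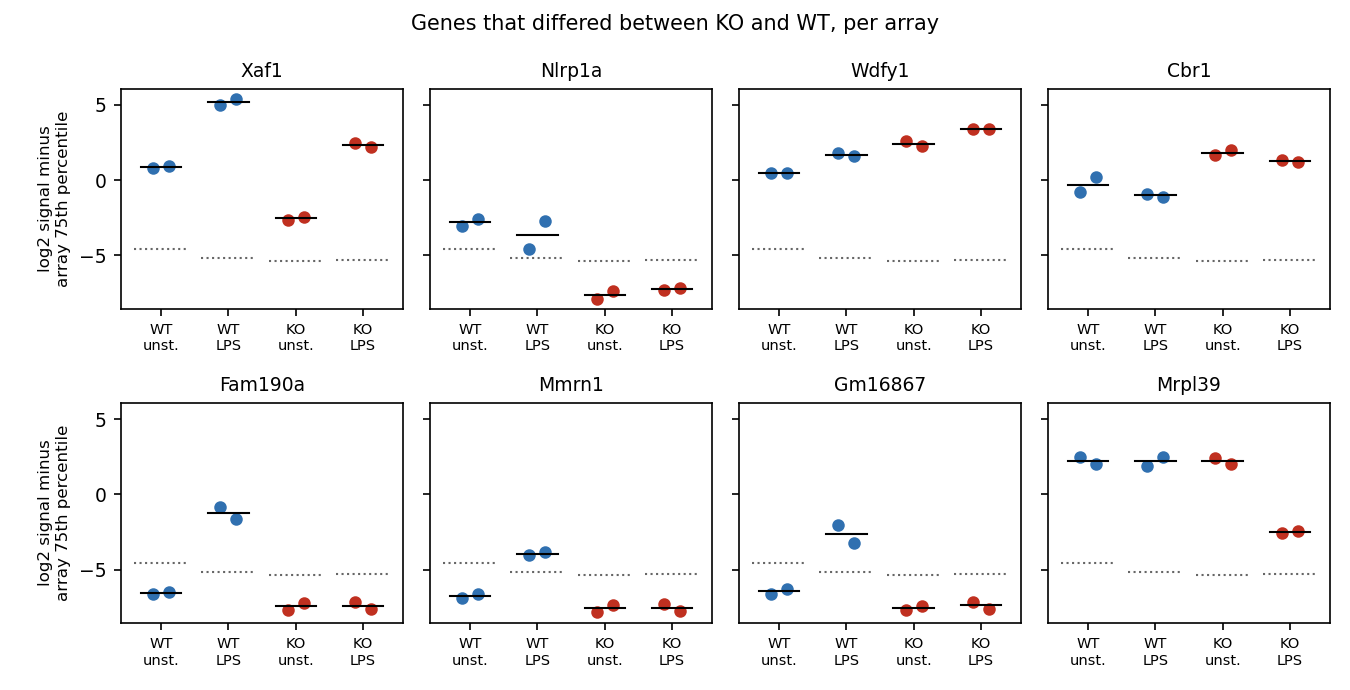
Scaled log2 signal (log2 signal minus the array's 75th percentile, vertical axis) on each array for Xaf1, Nlrp1a, Wdfy1, Cbr1, Fam190a, Mmrn1, Gm16867 and Mrpl39 in the 4 groups (horizontal axis), WT in blue and KO in red, with black bars for group means and a dotted line in each group for the mean of the arrays' lowest well-above-background signals. Mrpl39 has group means of 2.24, 2.19 and 2.20 in WT unstimulated, WT LPS and KO unstimulated cells and −2.51 in KO LPS cells.

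The same comparison after LPS asked whether activated DC differed by genotype. Mrpl39 on chromosome 16 (84718622 to 84724086) was lower in KO, at −4.70 ± 0.32 (SE, n = 2 arrays per group, adjusted p = 0.0148), and was well above background in both groups. Fam190a on chromosome 6 (61770138 to 61770197) was at least 16.9-fold lower in KO (adjusted p = 0.0148). Mmrn1, a platelet and endothelial protein gene also on chromosome 6 (60938883 to 60938942), was at least 2.62-fold lower (adjusted p = 0.0351), and Gm16867 on chromosome 14 (69984182 to 69984241), named after its values were seen, at least 6.47-fold (adjusted p = 0.044). Of 15400 genes, Mrpl39, Fam190a, Mmrn1 and Gm16867 were the 4 called, all lower in KO. At an unadjusted p under 0.05 the number was 187, again a smaller share than the 0.05 expected without any difference. The errors may thus be too large, and the few calls do not show that the genotypes were alike. The next smallest p values, without a call, were those of Xaf1 (−2.82 ± 0.27, adjusted p = 0.056) and of Fam164c (at least 1.63-fold lower), Hmx2 (at least 1.74-fold higher) and Frk (at least 1.64-fold lower), each at an adjusted p of 0.0789.

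None of the fixed genes linked to miR-155 or to DC cytokines was called after LPS, each with an adjusted p of 1 and n = 2 arrays per group. The arginase gene Arg2 had a log2 difference of 1.59 ± 1.18, Bach1 0.94 ± 0.35, Smad5, a BMP signalling gene, 0.83 ± 0.27, Picalm 0.73 ± 0.28, Jarid2 0.59 ± 0.33, Tab2 0.53 ± 0.27, Inpp5d 0.51 ± 0.26, Cebpb 0.22 ± 0.31, Sfpi1, which encodes PU.1, 0.09 ± 0.35, Socs1 −0.21 ± 0.68 and Fos 0.46 ± 0.70. Among cytokines and DC genes, Il6 had 0.06 ± 0.25, Tnf −0.01 ± 0.39, Il1b 0.12 ± 0.74, Il12b 0.07 ± 1.18, Il10 0.27 ± 1.42, Il23a 0.58 ± 0.62 and Ccr7 0.07 ± 0.92. As a group, the published miR-155 targets were higher in KO after LPS: 45 of 60 had higher means, with a median of 0.14 (camera adjusted p = 0.00109). None of its members was called, 0 passed adjusted over the list alone, and the list did not pass with an estimated correlation (adjusted p = 0.573). Its median was 0.17 with slide as a block and 0.19 within slide 2, and the call was lost without WT LPS replicate 1 (0.09) and without KO LPS replicate 2 (0.15). Cell cycle genes had a median of −0.29 with 32 of 36 lower (0 called, 0 adjusted over the list alone; adjusted p = 0.00148, and adjusted p = 0.896 with an estimated correlation), with −0.22 and −0.24 for the block and within slide 2. Without KO LPS replicate 1 that median was −0.03 and without WT LPS replicate 1 −0.34, both without a call, and without KO LPS replicate 2 it was −0.56. Interferon-stimulated genes had a median of −0.14 with 40 of 46 lower (0 called, 1 adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.896 with an estimated correlation). That direction turned with slide as a block, to a median of 0.02, and within slide 2, which leaves out WT LPS replicate 2, to 0.03. The median was −0.32 without WT LPS replicate 1 and −0.09, without a call, without KO LPS replicate 2. The neighbours of Mir155 had a median of −0.05 with Mrpl39 as the only member called (1 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.896 with an estimated correlation). That list did not pass without WT LPS replicate 1 (−0.20), WT LPS replicate 2 (−0.04) or KO LPS replicate 2 (−0.03), and the other 26 lists did not pass with all arrays.

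With slide as a block limma called 0 genes (237 at an unadjusted p under 0.05). In that fit Mrpl39 had −4.64 ± 0.37 (adjusted p = 0.0742), and Fam190a, Mmrn1 and Gm16867 had an adjusted p of 0.0715, 0.105 and 0.105. Within slide 2 Mrpl39 had −4.40, and 0 genes were called (271 at an unadjusted p under 0.05), and leaving out any 1 of the 8 arrays also gave 0 calls (197 to 334 at an unadjusted p under 0.05).

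Averaged over both states, 22 of 15400 genes were called, 4 higher and 18 lower in KO. At an unadjusted p under 0.05 the number was 411, also a smaller share than 0.05. A call on the average need not hold in each state. Of the 18 lower genes, 13 were well above background on both unstimulated WT arrays and 9 on both WT LPS arrays. Spag17 had fitted differences of −5.84 unstimulated and −0.17 after LPS, where it was dim in both genotypes, and Mrpl39 had −0.04 and −4.70. Xaf1 was lower by a log2 difference of −3.12 ± 0.19 (n = 2 arrays per group, adjusted p = 0.0146), Nlrp1a, dim on all KO arrays, had a fitted difference of −4.20 ± 0.42 (adjusted p = 0.0232), and Mrpl39 had −2.37 ± 0.23. Higher in KO were Wdfy1 by 1.83 ± 0.18 (adjusted p = 0.0232) and Cbr1, a carbonyl reductase gene on chromosome 16 (93610497 to 93610556), by 2.20 ± 0.26 (adjusted p = 0.0447). The other probes of Wdfy1 had 2.47 and −1.19. Fam190a (−3.53 ± 0.27), Mmrn1 (−2.22 ± 0.21) and Fam164c (−1.77 ± 0.20) were also lower, with fitted values that include a state in which the gene was dim in both genotypes. Interferon-stimulated genes had a median of −0.43 with 41 of 46 lower (1 called, 2 adjusted over the list alone; adjusted p = 1.6e-17, and adjusted p = 0.657 with an estimated correlation; −0.27 with the slide block). Oxidative phosphorylation genes had −0.11 (0 called; adjusted p = 0.033, and adjusted p = 0.932 with an estimated correlation; −0.18 with the block). They did not pass without WT unstimulated replicate 1 (−0.08), WT LPS replicate 1 (−0.14), WT LPS replicate 2 (−0.09), KO unstimulated replicate 2 (−0.02) or KO LPS replicate 1 (−0.11), and had −0.20 without KO unstimulated replicate 1. With slide as a block limma called 0 genes (332 at an unadjusted p under 0.05), Xaf1 having −2.96 ± 0.22 (adjusted p = 0.0887), and leaving out any 1 of the 8 arrays gave 0 to 8 calls. Across genes, the differences between genotypes in the unstimulated state and after LPS had r = 0.216 and rho = 0.303.

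Finally, the LPS response itself was compared between genotypes. The test called 7 genes, with a fitted difference of KO minus WT above 0 for 6 and below 0 for 1. At an unadjusted p under 0.05 the number was 219, also a smaller share of the genes than 0.05. Mrpl39 had a difference of −4.66 ± 0.45 (n = 2 arrays per group, adjusted p = 0.0441) and a fall with LPS in KO alone of the 2 genotypes. Hmx2, a developmental homeobox gene on chromosome 7 (138698994 to 138699053), had a fitted difference of 5.83 ± 0.43 (adjusted p = 0.0414) and was well above background on 1 of 2 unstimulated WT arrays, on both KO LPS arrays and on no others. The remaining 5, Spag17 among them (adjusted p = 0.0414), were well above background on no KO array in either state, so that no LPS response was measurable for them in KO. Interferon-stimulated genes had a larger response in KO by a median of 0.48, with 41 of 46 higher (0 called, 0 adjusted over the list alone; camera adjusted p = 2.34e-11, and adjusted p = 0.729 with an estimated correlation; 0.48 with the slide block). That largely restates the lower unstimulated signal in KO, as the KO minus WT medians were −0.60 unstimulated and −0.14 after LPS. Without KO unstimulated replicate 1 the median was 0.29. Ifit1, Oasl2, Oasl1 and Rsad2 had differences of 1.68 ± 0.36, 1.87, 1.49 and 1.29 without a call. Published miR-155 targets had a median of 0.22 with 39 of 60 higher (0 called, 0 adjusted over the list alone; adjusted p = 0.0377, and adjusted p = 0.729 with an estimated correlation; 0.22 with the slide block), and did not pass with any 1 of the 8 arrays left out (medians from 0.17 to 0.25). With slide as a block limma called 0 genes (243 at an unadjusted p under 0.05), and leaving out 1 array at a time gave 0 calls (234 to 362 at an unadjusted p under 0.05) except for 10 without WT unstimulated replicate 1. Replicate number as a block gave 0 calls (308 at an unadjusted p under 0.05), and a replicate block within each state, chosen after seeing the data, gave 23.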

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

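The test of other splits, the 3 tests on the genes lower in KO averaged over both states, and the slide and probe-sequence tests for Mrpl39 were chosen only after the result was seen. The first results here were picked out because the LPS response differed between the genotypes in a test of that difference. Mrpl39 had a response lower in KO by a log2 difference of −4.66. Fitted differences above 0 were found for AK034179 (3.63), AK089089 (4.17), NAP100574-001 (4.71), Spag17 (5.66), AK082037 (5.75) and Hmx2 (5.83), but the first 5 of these were well above background on no KO array, so that their values set the signal of unstimulated WT cells against background and show no response in KO. By the same kind of test, interferon-stimulated genes had a median difference of 0.48 and published miR-155 targets one of 0.22, and both lists lost the call with an estimated correlation (adjusted p = 0.729 for each). The value of 0.48 largely restates the lower unstimulated median of KO, −0.60 against −0.14 after LPS.

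For the 22 genes that differed between KO and WT on the average over both states, 18 splits with 2 arrays of each state on each side can be made. Of these, 5 gave as many calls, the real one included. That is too few splits for a share under 0.05. The highest other split gave 2006 calls, against 22 for the real one. It follows the replicate number in the labels, and its many calls point to a structure of the samples. The other splits with at least 22 calls, which gave 571, 89 and 49, also parted the arrays of both states or of the LPS state by replicate number, and the remaining splits gave 0 to 14.

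The first pattern is that 18 of the 22 genes were lower in KO on the average over both states, some of them in 1 state only. A slide effect was left open, because the genes behind the within-slide median of −1.67 (slide 1) were picked as lower on the same arrays and slide as a block left 0 of the 22 calls, and direct loss of repression by miR-155 was left untested, because the share of calls higher in KO, 18.2%, restates the pattern. Among the 18 lower genes, 3 neighbouring pairs lay within 1 Mb, on chromosome 14 (AK019700, Gm16867 and AK038254) and chromosome 6 (Mmrn1 and Fam190a). Random sets of genes had a median of 0 pairs (permutation p = 0.001). The permutation counted each gene as placed independently. Whether the 3 chromosome 14 probes report separate transcripts was not tested, so that p may overstate the clustering. A Slc25a37 probe near the chromosome 14 group was well above background on all 4 WT arrays and on 0 KO arrays. Its fitted differences, against KO signals near background, were −6.01 unstimulated and −8.03 after LPS. It was not the probe tested for its gene, as another was brighter. The other probes of Slc25a37 had differences of −0.18 and −0.39 on the average over both states. Probes of Entpd4 there, well above background on all 8 arrays and 1 of them overlapping the Gm16867 probe, had −0.80 and −0.54. A hypothesis is that the WT and KO mice differ in genomic segments besides Mir155. In the fit with that block Xaf1 went from −3.12 ± 0.19 to −2.96 ± 0.22, with a larger error and fewer residual degrees of freedom whose shares were not separated, and without sequence data the hypothesis stays open.

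The second pattern is the lower median of interferon-stimulated genes in unstimulated KO, −0.60 over 46 genes, which had an adjusted p of 0.471 with an estimated correlation. A slide effect as the only source was argued against by the median within slide 1, −0.40 with 40 of 46 genes lower. It rests on 1 KO array and on the same unstimulated arrays as the fit without KO unstimulated replicate 1. As the median moved from −0.60 to −0.40, a share of slide stays open. Array scaling was argued against by a median of −0.57 under quantile normalisation. A single array as the source was argued against because the median lay between −0.87 and −0.40 with any 1 of the 4 unstimulated arrays left out, the latter without KO unstimulated replicate 1. A lower general activation of the KO cells was left open. The median was −0.088 over 1416 other genes that rose with LPS in WT, but these were picked partly for low signal on the unstimulated WT arrays. The same arrays enter the KO minus WT difference and push that median upward, so the test cannot decide. Cytokines (−0.43, 17 of 22 lower) and NF-kB genes (−0.17, 20 of 28 lower), from lists fixed beforehand, had lower medians. The cytokine median was −0.28 without the 9 members dim in both groups, and the NF-kB list did not pass. Other lists that passed as higher with LPS in WT went both ways. MHC class I genes had −0.20 and DC maturation genes −0.11, but chemokines 0.15 and unfolded protein response genes 0.04, against −0.045 for all genes. A lower resting interferon signal in KO cultures may account for the pattern, as a hypothesis from the same data that measuring interferon in resting cultures of both genotypes would test, and a difference between the cultures of single animals cannot be excluded with 2 arrays per group.

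The third pattern is Mrpl39, the gene next to Mir155 among the listed neighbours, which was low in KO after LPS alone. A slide effect was argued against because the other arrays of the slide exceeded the KO LPS mean by at least 4.40 on the log2 scale. A sequence difference under the probe in KO mice was argued against by the unstimulated KO mean, which exceeded the KO LPS mean by 4.71. A general fall of mitochondrial ribosomal protein genes was argued against by the median difference in LPS response of 75 other such genes, 0.19. An effect of the altered Mir155 locus on its neighbour in activated cells may be proposed as a hypothesis, which was not tested. A second probe or a measurement by another method would test the low signal itself, not its cause.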

How the results depend on the processing

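The repaired normexp correction, the filter on detection in both groups and the replicate block within each state were chosen after seeing the data. Over all alternatives, 3662 of 3948 checks of list medians stayed on the same side of the threshold, 176 were stronger, 3 reversed and the others weaker, and the median had the other sign in 438, most of them lists below the threshold both times. Of 16861 checks of named genes 15572 stayed on the same side, with the same sign or a shift below 1 standard error. Of the others, 879 were weaker, 123 stronger and 13 reversed. The remaining 274 moved, as they were called in neither fit but changed sign by at least 1 standard error. Over all these checks of genes, 619 had the other sign. Counts are given in the order LPS in WT, LPS in KO, KO against WT unstimulated, after LPS and over both states, and difference of responses, which were 3106, 3208, 37, 4, 22 and 7. Planned normexp correction gave 709, 964, 0, 0, 1 and 0, with a correlation of responses of 0.702. Called genes rose in 425 and fell in 284 cases in WT, against 1460 and 1646. Its fit failed on KO LPS replicate 2, where the signal minus background of a spot reached −132662 and the correlation with the processed signal was 0.739. With such backgrounds replaced the last 4 counts were 2, 2, 3 and 0, the LPS counts 2613 and 2936, and r was 0.967. Under planned normexp the published miR-155 targets turned to −0.36 after LPS and −0.35 for the difference of responses, and interferon-stimulated genes to −0.41 for the latter. The LPS response in KO turned for Clec9a (0.55), Cd163 (0.012), Mcpt8 (0.44), Cpa3 (0.81), Ltf (0.96), Klra8 (0.52), Klrb1c (1.17), Cd2 (0.72) and Lat (0.95), as did KO against WT for Mmrn1 (0.91 after LPS, 0.14 over both states) and Fam164c (0.31). Casc1 turned to 0.47 without the filter, where another probe was chosen.

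Without the filter KO against WT gave 56 genes unstimulated and 2 after LPS, the difference of responses 0 and r 0.847, and with signal on all 8 arrays the last 4 counts were 1, 1, 3 and 0. Detection in both groups left 0 and 1. A slide block gave 5, 0, 0 and 0, and within 1 slide the first 4 counts were 1533, 441, 0 and 0, with fewer arrays. Only the 4 arrays compared gave 0 unstimulated and 0 after LPS. Quantile normalisation gave 14 for the difference of responses and shared 3019 of the 3106 calls in WT, and median scaling gave 7 genes after LPS. Trend and robust moderation gave 6 unstimulated, 4 over both states and 0 for the difference of responses, and every probe tested alone gave 0 for the last. Replicate number as a block gave 2 after LPS and 0 for the difference of responses. A replicate block within each state gave 42, 6, 31 and 23 for the last 4 counts. At an unadjusted p under 0.05 these were 1062, 632, 1160 and 612 genes, against 394, 187, 411 and 219 as reported. All 8 arrays correlated best with the same-numbered array of the other genotype in the same state, but the planned rule for pairing was not met. These r were 0.9829 to 0.9905, against 0.9705 to 0.9733 within a group. Variation shared by replicate number therefore stays in the errors of the reported KO against WT comparisons. Each reported number at an unadjusted p under 0.05 was a smaller share of the genes than the 0.05 expected without any difference. These tests may therefore miss differences between the genotypes. Leaving out 1 array gave 1442 to 2865, 1420 to 3106, 0 to 26, 0 to 0, 0 to 8 and 0 to 10, with r from 0.899 to 0.931, and a lone array was assumed to vary like the other groups. The median of all genes was −0.119 for LPS in KO under median scaling, and under normexp 0.13 there and −0.131 for KO against WT unstimulated, against 0.049 and −0.045 as reported. Where a limma count was 0, between 23 and 1009 genes had an unadjusted p under 0.05. Where no cause is named, the cause was not tested. The searches of 3′ untranslated regions with other site types, and of list members with such sites, were not run. Signal over background limits the comparisons of genotypes, since 30 of the 34 genes lower in unstimulated KO were not well above background there.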

Other observations

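The contrast by replicate number and the search of probe sequences were chosen only after the data were seen, while the prediction for the probe search was written before its result. With the 4 group means kept in the model, 86 genes differed between arrays of replicate number 2 and those of number 1 in limma, 40 higher and 46 lower in number 2. Cx3cr1, the fractalkine receptor of monocyte-lineage cells, was higher by 4.01 ± 0.38 (adjusted p = 0.0308), Cd79b, a B cell receptor component, by 2.44, Bcl11a, a transcription factor gene of lymphoid and plasmacytoid cells, by 2.14, Il18, a cytokine gene, by 1.98 ± 0.20, Tsc22d3, a glucocorticoid-induced gene, by 1.79, Bcl2l11, a pro-apoptotic gene, by 1.77 and Ccr7, the lymph node homing receptor, by 1.62 ± 0.19. Lower in number 2 were Car4, a carbonic anhydrase (−4.69), Ccl7 and Ccl2, monocyte-attracting chemokines (−3.93 and −3.61), Hbegf, a growth factor (−3.90), Stfa1, a protease inhibitor (−3.72), Dhrs9 (−2.29) and Pf4, a platelet chemokine (−1.82). Of the fixed lists, chemokines had a median of −0.45 with 3 members lower (camera adjusted p = 0.00618) and glycolysis genes one of −0.36 (adjusted p = 0.0169), while MHC class II genes had 0.39 (adjusted p = 0.0287) and sterol genes 0.31 (adjusted p = 0.0495). With an estimated correlation all 4 gave an adjusted p of 0.765.

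A hypothesis was that loss of miR-155 raises transcripts that hold its seed match. As 3′ untranslated regions were not available, the 60-base probe sequences were searched, which cover only a short stretch of each transcript. A match was AGCATTA, or GCATTAA, in which the first base is dropped and an A added at the end. The 95 genes with a match had a median KO minus WT difference after LPS of 0.11, against −0.01 for other genes. Of 376 other orders of the same bases, searched in the same way, 99.7% gave a lower median. The 28 genes with the longest type of match had a median of 0.20, and 0 of the 95 genes passed the test singly, against 4 of all genes. At an unadjusted p under 0.05 they were 2 genes, 1 higher and 1 lower in KO, and 187 genes. Camera gave p = 0.00466 for the set, and p = 0.0515 with an estimated correlation. In the unstimulated state 35.6% of the other orders lay below, and without WT LPS replicate 1 the share after LPS dropped to 78.2%. The result after LPS is consistent with a small effect of lost repression, as a hypothesis that rests in part on 1 array.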
